A study of Rattus norvegicus with 9 samples.

How the data were processed

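RNA from pancreatic islets of male Zucker Diabetic Fatty rats, a strain that becomes obese and diabetic through a defect in the leptin receptor, was hybridised to 9 Affymetrix rat whole-genome expression arrays, with 3 arrays in each of 3 groups. Per the labels, all arrays were biological replicates. The values of the deposited table were taken to be on a log2 scale because all were positive and lay in the narrow range that log2 summaries have, with no zeros, unlike a linear signal. Per the submitters' processing notes, RMA and MAS5 were used, and neither their roles nor their versions were given in the sources used here. The deposited log2 values were not identically distributed between arrays, since the standard deviation over probe sets ran from 1.649 to 1.997. Array brightness, not read depth, sets the precision here, and the number of arrays limits it.

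The table held 31099 probe sets. The 57 control probe sets were left out of the tests and used only to describe the arrays, which left 31042. Gene names came from the platform annotation and were updated through the gene table of assembly GRCr8, used for names only. Of the probe sets, 20826 had 1 gene symbol, 436 had several and were not named, and 9780 were not listed with a gene here. Of the symbols, 20758 matched by gene number, 2 by accession and 66 were kept as annotated, giving 14217 genes. Probe sets in the lowest 33.3% by mean log2 over the 9 arrays were left out, and 20695 were tested. A gene was represented by its probe set with the highest mean log2, which gave 11619 genes.

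Differences were estimated with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, a term per group, all 9 arrays sharing 1 estimate of the spread), with Benjamini-Hochberg adjusted p under 0.05 as the threshold. All differences are log2 differences, first group minus second. The 3 comparisons between pairs of groups and the moderated F test over the groups were fixed before the data were examined, as were the gene lists, the alternatives and the rule for named genes, except where a choice is said to have been made later. No covariate was used, since each group had an age of its own. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

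The 26 gene lists covered beta cell identity and function, other islet hormone cells, secretory granule and exocytosis, acinar, duct, macrophage and myeloid, lymphocyte, endothelial, stellate and extracellular matrix, Schwann and nerve, adipocyte and erythrocyte markers, PPAR target genes, mitochondrial fatty acid oxidation, fatty acid and triglyceride synthesis, cholesterol synthesis, the unfolded protein response, oxidative stress, inflammatory mediators, cell cycle, glycolysis, genes kept low in beta cells, oxidative phosphorylation, apoptosis regulators, ribosomal proteins, and stress and immediate early genes. The 25 lists with at least 5 measured members were tested with limma's camera at an inter-gene correlation of 0.01, adjusted over the lists, with an estimated correlation beside it. The position of a withdrawal array was its median, over the probe sets called between treated and untreated arrays, of its distance from the treated mean divided by the distance between both means. Limma's fry tested whether a list moved, on balance, in 1 direction. Each list's median was also placed among 10000 random lists matched on mean log2 in 20 bins. Named genes were, for each comparison, up to 10 genes with the largest positive and up to 10 with the largest negative difference among those past the threshold whose values did not overlap between groups, leaving out provisional symbols. To these were added up to 4 members of each list with the smallest p, and a fixed set of genes that included Ins1, Ins2, Gcg, Sst, Ppy, Pdx1, Mafa, Slc2a2, Pparg, Pdk4 and Cd36. Not all of these were printed.

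The alternatives were quantile normalization, centring on array medians, no filter or a filter on the lowest 50% of probe sets, eBayes with trend and robust settings, array weights estimated on the tested probe sets, a fit of only the 6 arrays compared, the replicate number as a block, each array left out in turn, a size floor of 1 on the log2 scale, and the mean over a gene's probe sets. Offsets before taking logarithms were planned only for linear values and were not run. Quantile normalization with the first treated array left out was added after the data were seen. The tests were checked on simulated data of 20695 probe sets. In the simulated comparison of treated with untreated arrays, limma recovered 74% of changes of 1 on the log2 scale and 99% of changes of 2, with 7 false calls. For withdrawal against untreated arrays it recovered 75% and 99% with 9 false calls, and for withdrawal against treated arrays 79% and 100% with 5. A simulated list shift was the 1 list called. The simulated probe sets were independent of each other and had no shift shared over an array. This check thus does not show how often probe sets or lists are called falsely on the real arrays.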

Results

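Gene expression was measured in isolated pancreatic islets of male Zucker Diabetic Fatty rats, an obese and diabetic strain. Rosiglitazone is an agonist of the nuclear receptor PPAR gamma and a drug for type 2 diabetes. The treated group received it in the diet, at 3 mg per kg body weight, from 5 weeks of age and was sampled at 9 weeks. The withdrawal group received it from week 5 to week 9 and was sampled 2 weeks after it was stopped, at 11 weeks of age. The untreated group was sampled at 13 weeks. Each group had 3 arrays, and 24 animals were randomised in the study. Treatment and age differed together between the groups, so no comparison separates them.

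The arrays differed in the spread of their values, and the difference between groups depended on probe set brightness. The standard deviation of log2 values was 1.895 ± 0.089 (SD, n = 3) on treated, 1.678 ± 0.036 on withdrawal and 1.731 ± 0.061 on untreated arrays. In the brightest decile of probe sets, the median difference was 0.49 for treated minus untreated, −0.15 for withdrawal minus untreated and −0.67 for withdrawal minus treated. In the dimmest decile the corresponding medians were −0.04, 0.03 and 0.06. Over the tested probe sets the median difference was 0.15, −0.02 and −0.19, and after quantile normalization it was 0.02, 0 and −0.03. Values below are as deposited unless a value after quantile normalization is named, and medians of most called gene lists as deposited are set beside those of random lists of like brightness. The first treated array had the steepest slope against the mean of the arrays, 1.118, and the second untreated array, at 0.941, lay among the withdrawal arrays, at 0.933 to 0.976. Acinar cell markers were bright on all arrays, with a mean of 13.0 ± 0.20 on treated, 12.8 ± 0.14 on withdrawal and 12.8 ± 0.10 on untreated arrays. Macrophage and myeloid markers ran from 7.245 to 8.879 on treated arrays, a wider range than on the others. The F test of limma called 7656 of 20695 probe sets as differing among the groups, and 5073 after quantile normalization.

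**Figure D1:**
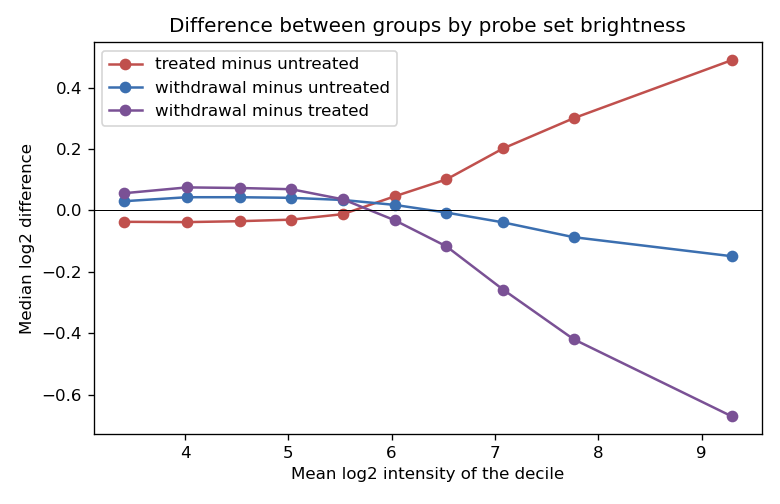
Median log2 difference between groups (y axis) against mean log2 value (x axis) in 10 groups of probe sets ordered by that value, with a line for each comparison. Treated minus untreated rose from −0.04 in the dimmest to 0.49 in the brightest decile, and withdrawal minus treated fell from 0.06 to −0.67.

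The comparison of treated with untreated rats asked how islet expression under rosiglitazone at 9 weeks differed from that of untreated islets at 13 weeks. Members of the lists of beta cell, other hormone cell, protein folding and immediate early genes rose on treated arrays, although no list was called with an estimated correlation (smallest adjusted p = 0.274). Trh, which encodes the precursor of thyrotropin-releasing hormone, rose by 2.73 ± 0.26 (SE, n = 3 per group; adjusted p = 0.000215) and by 2.36 after quantile normalization. The immediate early transcription factor Fos rose by 2.05 ± 0.36, the heat shock protein gene Hspa1a by 2.00 ± 0.34 and the endoplasmic reticulum gene Sdf2l1 by 1.82 ± 0.17. After quantile normalization these 3 rose by 1.53, 1.42 and 1.25. A further, dimmer probe set of Fos had a difference of the opposite sign that did not pass. Ambp, which encodes the alpha-1-microglobulin and bikunin precursor, fell by 2.73 ± 0.13 (adjusted p = 8.93e-07), and Rgs16, a regulator of G protein signalling, fell by 2.06 ± 0.18. They fell by 2.87 and 2.35 after quantile normalization. Txnip, the thioredoxin-interacting protein gene, fell by 1.49 ± 0.18 and by 2.05 after quantile normalization.

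Limma called 5817 probe sets, 4318 higher and 1499 lower on treated arrays, so that 74.2% of the calls were higher. After quantile normalization it called 3558, of which 45.1% were higher, and 2876 were called in the same direction in both. Of the tested probe sets, 42.9% had values that did not overlap between the groups as deposited, against 10% by chance. The shift with brightness moved many probe sets together, so this share does not measure how many genes were regulated. A fit of only the 6 arrays compared called 3209. Without the second untreated array the count was 2033 and without the first 3820. Among other genes with large differences, Reg3g was 3.81 higher, with a spread of 2.72 (SD) among treated arrays, and Amy1, a salivary and pancreatic amylase gene, was 2.48 higher with an SD of 1.55. Vsnl1, Nnat, P2ry1 and Col27a1 rose by 2.16, 2.14, 2.00 and 1.86. The metabotropic glutamate receptor gene Grm8 fell by 1.74, the neuropeptide gene Gal by 1.67, Casq1 by 1.63, Fyb1 by 1.62, Ly6al by 1.60 and Spetex2l2 by 1.53.

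Of 20 measured beta cell genes, 15 rose, 0 fell and 5 did not pass, with the same counts adjusted over the list alone, and the median was 0.66. It was 0.50 above the shift of all probe sets, but random lists of like brightness had a median of 0.44. The list was called higher by camera (adjusted p = 9.46e-05), with adjusted p = 0.684 with an estimated correlation. After quantile normalization 5 rose, with a median of 0.29. On the same arrays the medians of acinar and matrix markers lay at percentile 0 of random lists of like brightness, and those of endothelial, macrophage and lymphocyte markers at the 0.29th, 0.37th and 0.94th. The medians themselves were 0.037, 0.024, 0.002, 0.097 and −0.222, so only that of lymphocyte markers was below 0. Acinar markers had a mean near 13 on treated arrays, toward the top of the array scale, where a difference could go unmeasured. Duct markers lay at the 56.01th. Pax6, a transcription factor of islet cells, rose by 1.14 ± 0.17 and by 0.62 after quantile normalization, and the incretin receptor gene Gipr by 1.09 and 0.67. Nkx6-1 and Pdx1, transcription factors of beta cells, rose by 0.82 and 0.61, and Slc2a2, the glucose transporter of rat beta cells, by 0.68. These 3 were not past the threshold after quantile normalization, at 0.36, 0.26 and 0.15. The insulin genes Ins1 and Ins2 differed by 0.03 ± 0.11 (adjusted p = 0.874) and 0.12 ± 0.11 (adjusted p = 0.401), at mean log2 values of 14.2 and 14.3 on treated arrays. Both lay near the top of the array scale, where a difference in expression could go unmeasured, so these values do not show that insulin expression was unchanged. Mafa differed by 0.35 (adjusted p = 0.183) and changed sign, to −0.19, after quantile normalization.

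Of 10 genes of other islet hormone cells, 5 rose, and 6 adjusted over the list alone. Peptide YY (Pyy) rose by 1.5, somatostatin (Sst) by 1.29 and pancreatic polypeptide (Ppy) by 1.14, and these also passed after quantile normalization at 0.91, 0.77 and 0.77. Glucagon (Gcg) differed by 0.42 (adjusted p = 0.0579). Gcg was at 13.65 on treated and 13.23 on untreated arrays, toward the top of the array scale, where a difference could go unmeasured. This list was called higher by camera (adjusted p = 0.0313), with adjusted p = 0.684 with an estimated correlation, and adjusted p = 0.0619 without the third untreated array. Of 28 secretory granule genes, 17 rose, 18 adjusted over the list alone, led by Scg2 at 1.29 and Pcsk1n at 1.09. For these genes camera gave adjusted p = 0.0012, with adjusted p = 0.769 with an estimated correlation, and 0.166 after quantile normalization, where 8 rose and 3 fell.

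Of 29 genes of the unfolded protein response, 21 rose, 26 adjusted over the list alone, with a median of 0.69 against 0.46 for random lists of like brightness. The list test gave adjusted p = 2.09e-06, with adjusted p = 0.684 with an estimated correlation. Atf3 rose by 1.82, Creld2 by 1.27 and Wfs1, whose loss causes a form of diabetes in people, by 1.10. After quantile normalization 6 rose and 1 fell, with a median of 0.21. Of 24 stress and immediate early genes, 16 rose, among them Junb at 1.12, and adjusted over the list alone 20 rose and 1 fell. Their median was 0.99 against 0.38 for random lists of like brightness, and the list test gave adjusted p = 0.000447, with adjusted p = 0.684 with an estimated correlation, and 10 rose after quantile normalization.

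Of 54 oxidative phosphorylation genes, 23 rose, 33 adjusted over the list alone, with a median of 0.47 against 0.49 for random lists of like brightness, and Ndufb2 and Uqcrc2 rose by 0.76 each, neither past the threshold after quantile normalization. Camera gave adjusted p = 0.000162, with adjusted p = 0.902 with an estimated correlation. After quantile normalization none rose, 1 fell and the median was −0.07, so the direction of this list flipped with the scaling. Of 22 ribosomal protein genes, 15 rose, 20 adjusted over the list alone, with Rpl24 at 0.74 and a median of 0.53, close to that of random lists of like brightness. The adjusted p from camera was 0.000696, with adjusted p = 0.893 with an estimated correlation, and none passed after quantile normalization.

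Of 12 lymphocyte genes, 4 fell on both scales and also adjusted over the list alone. The interleukin 7 receptor gene Il7r fell by 0.90, and the T cell receptor components Cd3e and Cd3g fell by 0.74 and 0.495. Lymphocyte genes were dim, with list means of 5.75 on treated, 6.03 on untreated and 6.22 on withdrawal arrays. Medians over all probe sets of an array were 5.736 to 5.806. The list was called lower, with camera's adjusted p = 9.46e-05 and adjusted p = 0.274 with an estimated correlation. Of 34 stellate cell and matrix genes, 2 fell, Fn1 by 1.58 and Fbn1 by 0.72, and none adjusted over the list alone. Camera called this list lower (adjusted p = 0.0313), with adjusted p = 0.936 with an estimated correlation, although its median was 0.02 and its mean 0.07, where random lists of like brightness had a median of 0.47. Its median was 0.28 (adjusted p = 0.583) without the second treated array and 0.16 (adjusted p = 0.154) without the third untreated array. After quantile normalization 16 fell, with a median of −0.40. Of 24 PPAR target genes, 2 rose and 1 fell on both adjustments, that over all probe sets and that adjusted over the list alone. After quantile normalization 0 rose and 5 fell, with a median of −0.21. Pdk4 and the fatty acid binding protein gene Fabp4 rose by 0.77 and 0.80 and Ucp3 fell by 0.47. Pdk4 and Fabp4 were not past the threshold after quantile normalization, at 0.48 and 0.37. The list was called lower (camera adjusted p = 0.0313), with adjusted p = 0.684 with an estimated correlation, at a median of −0.08 and a mean of 0, where random lists of like brightness had a median of 0.27. It was not called without the second treated array (adjusted p = 0.0702) or without the first untreated array (adjusted p = 0.114). With each of the 9 arrays left out in turn, Fbn1 was not called in 8 fits, Ucp3 and Fabp4 in 2, and Pdk4, Fn1 and Cd3e in 1. Pparg itself differed by 0.09 (adjusted p = 0.628) and Cd36 by 0.27 (adjusted p = 0.354). Pparg was dim, at mean log2 values of 5.25 on treated and 5.16 on untreated arrays, below the array medians. Its values thus do not show that Pparg expression was unchanged.

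Camera did not call the other 15 lists tested. Among 17 cholesterol synthesis genes, Idi1 fell by 0.53, a call absent from 8 of 9 fits that left out an array, and none fell adjusted over the list alone, and camera gave adjusted p = 0.119 as deposited and 0.00884 after quantile normalization. For acinar, duct and macrophage markers camera gave adjusted p = 0.411, 0.592 and 0.247, and for endothelial, Schwann cell and adipocyte markers 0.0519, 0.119 and 0.357. It gave 0.725 for fatty acid oxidation, 0.748 for fatty acid and triglyceride synthesis, 0.909 for oxidative stress and 0.714 for inflammatory mediators. Cell cycle, glycolysis, genes kept low in beta cells and apoptosis regulators gave 0.714, 0.714, 0.247 and 0.491. After quantile normalization endothelial markers and genes kept low in beta cells were called lower, with adjusted p = 0.00112 and 0.0155. Both calls were lost there at adjusted p = 0.413 with an estimated correlation, as was that of cholesterol synthesis genes. Of the genes in these lists, the metallothionein gene Mt1 rose by 1.5 and the NF-kappa-B inhibitor gene Nfkbia by 1.28. The erythrocyte list had 4 measured members and was not tested; its hemoglobin gene Hbb rose by 1.14.

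**Figure D2:**
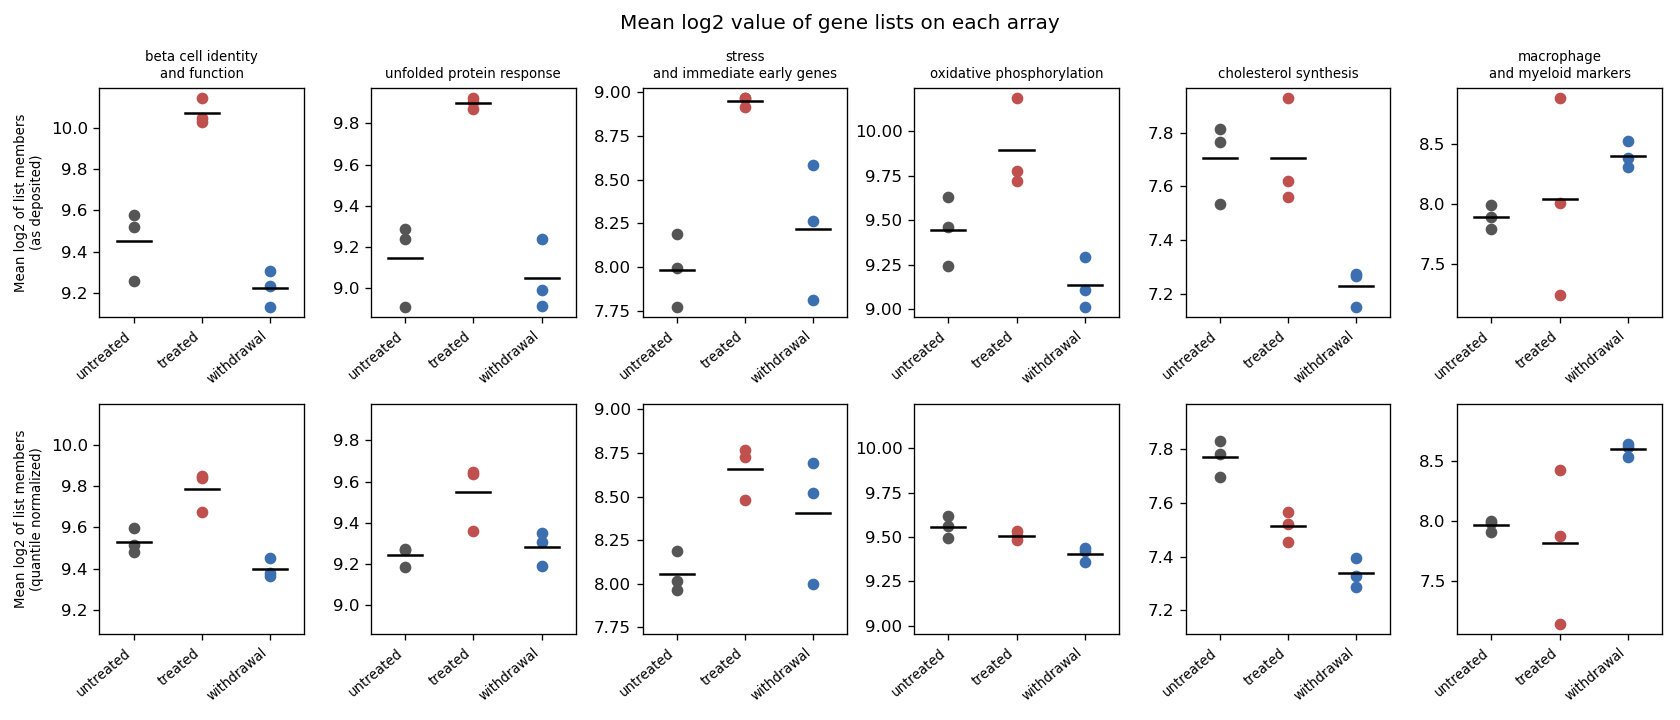
Mean log2 value over the members of 6 gene lists on each array (points) and the mean of each group (bars), as deposited (upper row) and after quantile normalization (lower row). The beta cell list was at 10.07 ± 0.06 on treated, 9.45 ± 0.17 on untreated and 9.22 ± 0.09 on withdrawal arrays as deposited (SD, n = 3).

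The comparison of withdrawal with untreated rats set 11-week-old rats, 2 weeks after the drug was stopped, against untreated rats of 13 weeks. Differences in it may come from the earlier treatment or from age. In the fit of all 9 arrays with equal weights, 33 probe sets passed and 32 of these were lower on withdrawal arrays, but both the number and the share that were lower changed with the arrays and weights used. Ambp fell by 2.17 ± 0.13 (adjusted p = 1.24e-05), Rgs16 by 1.81 ± 0.18 and Txnip by 1.44 ± 0.18. Mid1ip1, a lipogenic regulator, fell by 1.32, the growth factor gene Hbegf by 1.31 and Idi1, an enzyme of isoprenoid synthesis, by 1.27. Trh was the gene that rose, by 1.60 ± 0.26 (adjusted p = 0.0384).

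Limma called these 33, 1 higher and 32 lower, against 1553 at an unadjusted p under 0.05. As deposited, values did not overlap for 18% of the probe sets, against 10% by chance. With array weights it called 3275, of which 771 were higher, and in a fit of only the 6 arrays compared 494, of which 172 were higher. After quantile normalization it called 87, of which 7 were higher, and all 33 were kept. The count was 7 without the first untreated array, without the third untreated array and without either of the first and second withdrawal arrays, and 11 without the third withdrawal array. It was 398, of which 105 were higher, without the first treated array, 54 without the second and 21 without the third, which enter through the shared estimate of the spread. Spetex2l2, Matk, Rprml and C5h8orf88 fell by 1.80, 1.59, 1.38 and 1.32. With each of the 9 arrays left out in turn, Trh was not called in 7 fits (highest adjusted p = 0.265), Mid1ip1 in 6, Idi1 and C5h8orf88 in 5, and Txnip and Rprml in 4. Ambp, Rgs16, Hbegf, Spetex2l2 and Matk were called in each of these fits. Ins1 and Ins2 differed by −0.07 (adjusted p = 0.928) and 0.00 (adjusted p = 0.997). Pdx1, Mafa, Sst and Gcg differed by −0.46, −0.74, −0.64 and −0.34, and none of these passed. For Ins1, Ins2 and Gcg, toward the top of the array scale, a difference could go unmeasured.

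Camera called 12 of 25 lists in this comparison, and none with an estimated correlation, where the smallest adjusted p was 0.474. Fry called 0 lists here (smallest adjusted p = 0.181), with 4 at an unadjusted p under 0.05, and 5 after quantile normalization. It called 6 in treated against untreated and 12 in withdrawal against treated arrays, and 14 and 9 after quantile normalization. Of 17 cholesterol synthesis genes, 1 fell, and 9 adjusted over the list alone, with a median of −0.43. Their test gave adjusted p = 2.76e-08, with adjusted p = 0.547 with an estimated correlation. Msmo1, Insig1 and Fdft1 differed by −1.0, −0.78 and −0.77. They passed adjusted over the list alone, and over all probe sets they passed after quantile normalization, where 5 members of the list fell. As deposited no member of the other lists named here passed over all probe sets. After quantile normalization Scg5 of the secretory granule list fell by 0.62, Pklr of the glycolysis list by 0.72 and Gpd1 of the PPAR target list by 0.51. Camera called macrophage and myeloid markers higher (adjusted p = 1.16e-10, and adjusted p = 0.567 with an estimated correlation), with a median of 0.49, and Mrc1 and Fcgr2b at 1.33 and 1.26. It called stellate cell and matrix genes higher (adjusted p = 0.000125, and adjusted p = 0.697 with an estimated correlation), with Postn at 1.98. Inflammatory mediators were called higher (adjusted p = 0.000313, and adjusted p = 0.567 with an estimated correlation), with complement C3 at 1.5. Cell cycle genes were called higher with a median of 0.16 (adjusted p = 3.71e-07, and adjusted p = 0.567 with an estimated correlation). Oxidative phosphorylation genes were called lower with a median of −0.30 (adjusted p = 9.71e-12, and adjusted p = 0.567 with an estimated correlation). Beta cell genes were called lower with a median of −0.28 (adjusted p = 0.000705, and adjusted p = 0.567 with an estimated correlation), and 3 fell adjusted over the list alone. Secretory granule genes were called lower with a median of −0.24 (adjusted p = 0.0076, adjusted p = 0.216 after quantile normalization, adjusted p = 0.0702 without the first untreated array, and adjusted p = 0.697 with an estimated correlation). Fatty acid oxidation genes were called lower with a median of −0.24 (adjusted p = 0.00161), and fatty acid and triglyceride synthesis genes with a median of −0.19 (adjusted p = 0.00255), both with adjusted p = 0.567 with an estimated correlation. Lymphocyte markers were called higher with a median of 0.16 (adjusted p = 0.000368, and adjusted p = 0.474 with an estimated correlation). Stress and immediate early genes were called higher with a median of 0.21 (adjusted p = 5.38e-05, adjusted p = 0.0581 without the third withdrawal array, and adjusted p = 0.567 with an estimated correlation). Adjusted over the list alone, 6 fatty acid and triglyceride synthesis genes and 2 secretory granule genes fell and 1 lymphocyte gene rose. Among glycolysis genes, which were not called, Pklr and Pfkl differed by −0.71 and −0.62. Random lists of like brightness had medians of −0.07 for cholesterol synthesis, −0.17 for oxidative phosphorylation, −0.14 for beta cell and −0.12 for secretory granule genes. They had −0.09 for fatty acid oxidation and −0.07 for fatty acid and triglyceride synthesis genes, and between −0.15 and 0.02 for the 6 lists called higher.

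After quantile normalization 11 of these 12 lists were called in the same direction, and secretory granule genes were not, at a median of −0.07. With an estimated correlation camera called none there (smallest adjusted p = 0.152). The medians were then 0.62 for macrophage and myeloid, 0.28 for matrix, 0.17 for inflammatory, 0.20 for cell cycle, 0.17 for lymphocyte and 0.37 for stress and immediate early genes. They were −0.47 for cholesterol synthesis, −0.16 for oxidative phosphorylation and −0.13 for beta cell genes. Fatty acid oxidation and fatty acid and triglyceride synthesis genes were both at −0.14. Ribosomal protein genes were not called as deposited (adjusted p = 0.935), but were called higher after quantile normalization (adjusted p = 0.00213, and adjusted p = 0.344 with an estimated correlation), where their median changed from −0.06 to 0.08. As deposited they were called lower without the third withdrawal array (adjusted p = 0.0376) and higher without the third untreated array (adjusted p = 0.0406). PPAR target genes were called lower and genes kept low in beta cells higher after quantile normalization (adjusted p = 0.015 and 0.00538), with adjusted p = 0.255 and adjusted p = 0.323 with an estimated correlation.

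The comparison of withdrawal with treated rats set 11-week-old rats, 2 weeks after the drug was stopped, against 9-week-old rats under the drug. Members of the lists of hormone cell, beta cell and protein folding genes fell on withdrawal arrays and 6 of 12 lymphocyte genes rose, although no list was called with an estimated correlation (smallest adjusted p = 0.107). Sst fell by 1.93 ± 0.17 (SE, n = 3 per group; adjusted p = 0.000329) and by 1.21 after quantile normalization. Ppp1r1a, an inhibitor of protein phosphatase 1, fell by 1.81 ± 0.14 and by 1.08 after quantile normalization. The transcription factor genes Fos, Egr1 and Etv1 fell by 1.74, 1.71 and 1.66, although a further probe set of Fos was called in the opposite direction. Grm8 rose by 2.12 ± 0.22 and Casq1 by 1.97 ± 0.16, and by 2.65 and 2.06 after quantile normalization.

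Limma called 9057 probe sets, 2312 higher and 6745 lower on withdrawal arrays, so that 25.5% were higher. After quantile normalization it called 6032, of which 49.9% were higher, and 4891 were called in the same direction in both. Without the second withdrawal array the count was 5587. As deposited, values did not overlap for 53.9% of the probe sets, against 10% by chance, a share that the shift with brightness also raises. Ly6al, Stk36, Trhr and Ankrd60 rose by 1.86, 1.66, 1.66 and 1.64, and Nacc2, Trpv1, Dgkk and Slc24a4 by 1.58, 1.5, 1.48 and 1.48. Tmsb15b2, Chic1, Vsnl1, Hbb and Nnat fell by 1.64, 1.60, 1.58, 1.57 and 1.55.

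Of 20 beta cell genes, 17 fell, 18 adjusted over the list alone, with a median of −0.92 against −0.61 for random lists of like brightness. The list was called lower (camera adjusted p = 9.09e-06), with adjusted p = 0.696 with an estimated correlation, and 10 fell after quantile normalization. On the same arrays the medians of acinar, macrophage and matrix markers lay at percentile 100 of random lists of like brightness, and those of lymphocyte, endothelial and duct markers at the 99.92th, 96.66th and 76.95th. The medians themselves were −0.091, 0.339 and 0.202 for the former and 0.401, −0.164 and −0.349 for the latter. For acinar markers, with a mean near 13 on treated arrays, a difference could go unmeasured. Pax6, Nkx6-1, Pdx1 and Nkx2-2 fell by 1.46, 1.25, 1.07 and 1.07, and by 0.82, 0.70, 0.66 and 0.53 after quantile normalization. Mafa fell by 1.08 and Slc2a2 by 1.01, the latter not past the threshold after quantile normalization at −0.30. Ins1 and Ins2 differed by −0.10 and −0.12, near the top of the array scale, and did not pass. Of 10 genes of other hormone cells, 7 fell on both adjustments, that over all probe sets and that adjusted over the list alone, among them Pyy by 1.37, Ppy by 1.14 and Gcg by 0.76. The list test gave adjusted p = 0.0236, with adjusted p = 0.696 with an estimated correlation, and 6 fell and 1 rose after quantile normalization. Of 28 secretory granule genes, 22 fell, also adjusted over the list alone, including Pcsk1n by 1.25 and Syt13 by 1.10, with camera's adjusted p = 0.000103 and adjusted p = 0.696 with an estimated correlation. After quantile normalization 9 fell and 1 rose, and the median changed from −0.79, against −0.59 for random lists of like brightness, to −0.23.

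Of 29 unfolded protein response genes, 26 fell, 27 adjusted over the list alone, with Dnajb9, Sdf2l1 and Pdia3 at −1.25, −1.24 and −1.10. The median was −0.88 against −0.65 for random lists of like brightness, with camera's adjusted p = 2.33e-06 and adjusted p = 0.696 with an estimated correlation, and 7 fell after quantile normalization. Of 54 oxidative phosphorylation genes, 51 fell, also adjusted over the list alone, including Ndufb2 by 0.96 and Cox7b by 0.91, neither past the threshold after quantile normalization. The median was −0.79 against −0.70 for random lists of like brightness, and the list gave adjusted p = 2.82e-08, with adjusted p = 0.696 with an estimated correlation. After quantile normalization 3 fell and camera gave adjusted p = 0.0858. Of 22 ribosomal protein genes, 20 fell, and 22 adjusted over the list alone, with Rpl24 at −0.70. Camera called the list lower (adjusted p = 0.00256, and adjusted p = 0.696 with an estimated correlation), although its median of −0.62 was above the −0.76 of random lists of like brightness, at the 96.95th percentile. After quantile normalization 1 rose and the median was 0.04, so the direction flipped with the scaling.

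Of 12 lymphocyte genes, 6 rose on both scales, 7 adjusted over the list alone, with Il7r, Cd3e and Cd3g at 1.08, 0.88 and 0.69. These genes were dim, with list means of 6.22 on withdrawal and 5.75 on treated arrays. The list was called higher (adjusted p = 8.85e-07), with adjusted p = 0.107 with an estimated correlation. Of 24 macrophage and myeloid genes, 2 rose, 1 adjusted over the list alone, and 12 after quantile normalization. Camera gave adjusted p = 1.52e-05, with adjusted p = 0.696 with an estimated correlation, and without the second treated array its median was −0.06 with adjusted p = 0.0773. The macrophage gene Aif1 rose by 0.73, while Csf1r and Mrc1 differed by 0.76 and 0.99 without passing. Of 34 stellate cell and matrix genes, Fbn1 rose by 0.94 and Col6a3 differed by 0.70, with 23 rising after quantile normalization and none adjusted over the list alone as deposited. Camera gave adjusted p = 9.99e-05, with adjusted p = 0.696 with an estimated correlation, and without the second treated array its median was −0.22 with adjusted p = 0.26. Cell cycle genes were called higher (adjusted p = 0.009, and adjusted p = 0.696 with an estimated correlation) at a median of −0.03 and a mean of −0.01, against −0.12 for random lists of like brightness and above the shift of all probe sets, and were not called after quantile normalization (adjusted p = 0.138) or without the second treated array (adjusted p = 0.183). Of 24 stress and immediate early genes, which camera did not call (adjusted p = 0.0958), 15 fell and 1 rose, with a median of −0.87 against −0.52 for random lists of like brightness. After quantile normalization 3 fell and 1 rose, 0 adjusted over the list alone, with a median of −0.18. Endothelial markers and genes kept low in beta cells were called higher after quantile normalization (adjusted p = 0.0275 and 7.74e-05), with adjusted p = 0.52 and adjusted p = 0.324 with an estimated correlation. Pdk4, Fabp4, Mt1 and Insig1 fell by 0.89, 1.19, 1.45 and 1.09.

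**Figure D3:**
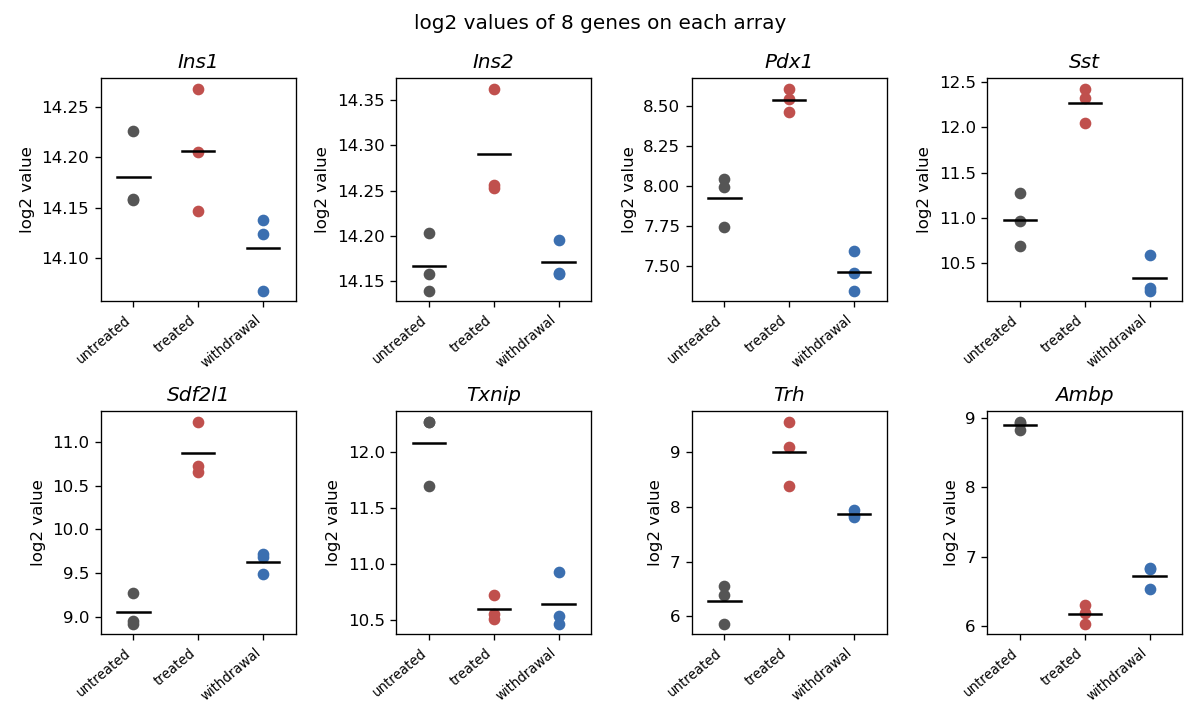
The log2 values of 8 genes on each array (points) with the mean of each group (bars), each panel on its own scale. Ambp was at 8.90 ± 0.07 on untreated, 6.17 ± 0.13 on treated and 6.73 ± 0.17 on withdrawal arrays (SD, n = 3).

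Of the probe sets called in both comparisons with untreated arrays, 24 went in the same direction, 1 higher and 23 lower, and none in opposite directions. Independent lists of these sizes would share 0.209 higher and 2.32 lower. Simulated unchanged groups sharing the untreated arrays gave a mean of 0.01 and at most 1 in 100 simulations. With no real difference and independent noise, hardly any probe set could be called there, so these simulations set no benchmark for the 24. The untreated arrays were too few to be split, so part of the excess may come from the shared controls. After quantile normalization the overlap was 69. With array weights it was 460, 149 higher and 311 lower, and with the replicate block 37. The overlap was 142, of which 41 were higher, without the first treated array, 11 without the third withdrawal array, and 7 without either of the first and the second withdrawal array and without either of the first and the third untreated array.

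The withdrawal arrays were placed between the other groups over the 5817 probe sets called in treated against untreated arrays, where 0 is the treated and 1 the untreated mean. They lay at 1.167, 1.222 and 0.975, with a mean of 1.121 ± 0.129 (SD, n = 3), and at 1.015 ± 0.098 after quantile normalization. Over those probe sets the withdrawal arrays thus had a median position near the untreated arrays, while Ambp, Rgs16, Txnip and Spetex2l2 were lower than on untreated arrays. Without untreated arrays of the same age, a lasting effect of the drug cannot be told apart from a difference with age.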

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

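All tests weighed here were chosen after the results they concern had been seen, except the counts over other splits of the arrays. A signal outside the main measurement was the bacterial hybridization controls, which hold no islet RNA: they were 0.57 higher on treated than on untreated arrays on the log2 scale (exact permutation test, two-sided, p = 0.3; the smallest possible with 3 against 3 is 0.1).

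Bright probe sets were higher on treated than on untreated arrays. A difference in hybridization or signal could account for it, since the controls were 0.57 higher, but their values overlapped between the groups and the first treated array, with the steepest slope, was at 9.788 against 9.874 on an untreated array. A difference in RNA integrity was also left open: the actin 3′ minus 5′ value was lower by −0.218 on treated arrays (exact permutation test, two-sided, p = 0.1), while the Gapdh value differed by −0.117 and overlapped. The technical explanations and an effect of treatment or age cannot be told apart, because each group had its own age and treatment and 3 arrays.

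On treated arrays the respiratory chain and ribosomal protein lists were higher, but among random lists of like brightness their medians reached at most the 53.8th percentile, consistent with the shift that all bright probe sets shared. The medians of the beta cell, other hormone cell, unfolded protein response and immediate early lists lay at the 99.33th percentile or above. The secretory granule list, also called higher, lay at the 91.12th. Random lists were drawn gene by gene, while members of a list may vary together over arrays. These percentiles thus do not exclude the shift of bright probe sets as the whole cause. After quantile normalization the beta cell list mean still rose by 0.257 ± 0.067 (SE over arrays) and that of other hormone cells by 0.38 ± 0.061. The unfolded protein response and immediate early list means rose by 0.305 ± 0.098 and 0.601 ± 0.112. A larger share of islet cells could contribute. Relative to random lists of like brightness, matrix, endothelial, macrophage and lymphocyte markers lay at the 0.94th percentile or below, although duct markers lay at the 56.01th. As deposited, however, the list means differed by 0.074 ± 0.434 for matrix, −0.017 ± 0.155 for endothelial and 0.151 ± 0.475 for macrophage markers. Of these lists only lymphocyte markers, at −0.275 ± 0.068, fell beyond 2 SE. With so few arrays per group, 2 SE is a descriptive mark here and not a test. After quantile normalization endothelial markers, at −0.273 ± 0.066, fell beyond 2 SE as well. Acinar markers lay at percentile 0, but at a mean near 13 on treated arrays a difference in them could go unmeasured. Of the 25 acinar genes, 2 were called higher and 0 lower as deposited. After quantile normalization lists of other cell types moved apart by up to 0.294 ± 0.135 (duct against matrix, 0.173 ± 0.158 as deposited). The immediate early list then rose beyond the beta cell list by 0.344 ± 0.083. Beyond the other hormone cell list it rose by 0.221 ± 0.171, within 2 SE, but by 0.326 ± 0.146, beyond 2 SE, as deposited. The share of islet cells thus stays open. Handling of the islets before lysis may raise immediate early genes, whose list lay at percentile 100, but the beta cell list at 99.9 moved as well, so handling stays open, as do treatment and age.

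Myeloid and matrix genes were higher on withdrawal than on treated arrays after quantile normalization, to which more tissue from outside the islets could contribute, but without the second treated array the myeloid rise fell from 0.781 ± 0.369 (SE over arrays) to 0.449 ± 0.273. The matrix list rose by 0.775 ± 0.298, at a gap to the myeloid list of 0.006 ± 0.075, so these 2 lists moved alike. The rise of the myeloid list exceeded that of the duct list by 0.622 ± 0.19, and by 0.446 ± 0.116 without the second treated array. That gap was 0.555 ± 0.2 over the 11 duct members other than keratins and Epcam, some of which islets also express. Over these members it was 0.571 ± 0.342, within 2 SE, without the third treated array. The myeloid list thus rose more than the duct list on these arrays. With so few arrays per group, however, a gap beyond 2 SE is a description and not a test. More of every outside cell type alike therefore stays open as the whole cause. The gaps to the acinar list, 0.759 ± 0.492, and to the endothelial list, 0.602 ± 0.335, were within 2 SE, but rested on single arrays: they were 0.341 ± 0.449 and 0.3 ± 0.219 without the second treated array, and 1.192 ± 0.402 and 0.854 ± 0.363, beyond 2 SE, without the first. Acinar genes, at a mean near 13 on treated arrays, could also hide a small rise, so more acinar tissue cannot be told apart from a change in myeloid cells with treatment or age, and outside tissue poor in duct cells was not tested.

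For the counts of probe sets, 3 arrays against 3 make 10 splits, too few for a share under 0.05. The real splits gave 5817, 33 and 9057 calls, and the highest of the other splits gave 0 in each comparison, so that 1 of 10 splits was as large each time. For called lists, the real splits gave 10, 12 and 10, and the highest other splits 14, 13 and 15, with 3, 3 and 4 of 10 splits as large. For the F test, 1 of 100 splits of the 9 arrays, the real one, gave as many as 7656 calls. The highest other split drawn gave 5680, so the real grouping gave the most calls, but another grouping also gave a large count.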

How the results depend on the processing

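Quantile normalization with the first treated array left out was chosen after seeing the data; the other alternatives were planned, and offsets before logarithms did not apply. For what moved, the cause was not tested unless stated. Quantile normalization gave 3558, 87 and 6032 calls for treated against untreated, withdrawal against untreated and withdrawal against treated, 5073 for the F test and an overlap of 69. It reversed oxidative phosphorylation in treated against untreated (−0.074) and ribosomal proteins in withdrawal against untreated (0.082) and against treated (0.037), with Rpl24 at 0.023. With the first treated array also left out, these lists were at −0.082, 0.082 and 0.037, and withdrawal against untreated had 395 calls. Array weights gave 3275 calls for withdrawal against untreated and an overlap of 460. A fit of only the 6 arrays compared gave 3209 calls for treated and 494 for withdrawal against untreated. Replicate numbers did not clearly pair the arrays, and a shared batch stays open. Of 9 same-number correlations of deviations, 5 exceeded 0.1 (range −0.283 to 0.504), and those between different numbers ran from −0.485 to 0.406. For 1 array the best match in both other groups had its own number. The replicate block gave 50 calls for withdrawal against untreated and an overlap of 37. The size floor, which only removes calls, left 364, 688 and 825 for treated against untreated, withdrawal against treated and the F test, an overlap of 14, and a position of 0.94. With an estimated correlation camera called 0, 0 and 0 lists. Leaving out each array gave 2033 to 6319 calls for treated against untreated, 7 to 398 for withdrawal against untreated, 5587 to 9511 for withdrawal against treated, 4768 to 8609 for the F test and overlaps of 7 to 142. The position ran from 1.019 to 1.192, and called lists ran from 8 to 15, 12 to 15 and 7 to 14 in the 3 comparisons. It moved the median of matrix genes in treated against untreated between −0.243 and 0.284, and that of ribosomal proteins in withdrawal against untreated between −0.197 and 0.06. Centring, both filters and the variance prior kept each of these counts within 1.5 times. Array signal over background limits dim probe sets.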

Other observations

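Except where said, the tests in this part were written before the members' own values were looked at, although the medians of fixed lists holding some of the members had been seen. Rsad2, Ifit2 and Slfn4, genes induced by interferon, had been noticed among the genes lower on treated arrays, and a list of 23 other interferon-induced genes was written. Of the 17 measured, 5 were lower and none higher on treated than on untreated arrays past the limma threshold, including Mx2 (−0.59), Isg15 (−0.56), Irf7 (−0.54), Rtp4 (−0.65) and Oas1a (−0.45). The median was −0.17, at the 0.55th percentile of random lists of like brightness, under the limit of 2.5 set beforehand, and after quantile normalization it was −0.19 at the 1.16th percentile. In a check added afterwards, the 15 members outside the fixed lists had a median of −0.09 at the 4.01th percentile, above that limit. Lymphocyte markers were lower on the same arrays, with 4 of 12 past the threshold and a median of −0.22 at the 0.94th percentile. A lower interferon response on treated arrays may be followed up as a hypothesis, but it was not separated from a smaller share of lymphocytes or from age, and these values leave it open.

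Txnip, Rgs16, Ambp, Mid1ip1 and Pklr had lower values on treated or withdrawal than on untreated arrays, and Txnip and Pklr are known to respond to glucose. The hypothesis of lower glucose exposure in both groups was tested on 18 further genes known to respond to glucose, of which 15 were measured. Their medians were 0.21 for treated and 0.01 for withdrawal against untreated arrays, at the 30.4th and 87.9th percentiles of matched lists, where the limits set beforehand were a value under 2.5 in both for the hypothesis and one above the median of matched lists in both against it. After quantile normalization they lay at the 26.1th and 50.7th percentiles. In the check added afterwards, the 9 members outside the fixed lists lay at the 64.5th and 90.2th percentiles, both above the median. The test, with 87.9 as the higher percentile, met neither limit over all 15 members on either scale, so it gave the hypothesis no support and did not exclude it. Blood glucose was not analysed here.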
